A study of Mus musculus with 14 samples.

How the data were processed

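RNA sequencing of 14 libraries of mouse embryonic fibroblasts was used. The cells carried the 4 reprogramming factors Oct4, Sox2, Klf4 and c-Myc and in addition Cdk9-DN or its control vector, and were collected 3, 4, 5 or 10 days after infection. The deposited values are FPKM (fragments scaled by transcript length and depth) with a lower and an upper bound, in 1 table per library, computed by the authors. Per the submitters' processing notes, reads were handled with CASAVA 1.8.2, aligned with TopHat2 2.0.10 and quantified with Cufflinks 2.2.1, and the genome builds were named mm9 and NCBIM37. Read counts were not used here. Coordinates are those of the deposited tables (mm9). A GENCODE M21 annotation on a later build gave only the gene type, the exon number and, for the depth, the transcript length. It held 22524 (83.5%) of the 26962 gene identifiers listed in any library.

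Values of the 16 genes with several entries under 1 identifier were summed, and the 1 entry with a failed status (Triap1) was left out. A gene that a library did not list was treated as having no value there, never as 0. Of the genes listed in all or some libraries, 7460 had an FPKM of at least 1 in at least 2 of the 12 libraries of days 4, 5 and 10. Of these, 3491 were listed in all 12 libraries, 5424 in every one of the 6 groups, and 3969 were missing from at least 1 library. Among the testable genes with the required groups, small RNA genes and processed pseudogenes were kept. Values of exactly 0 were kept as deposited. In each group, 196 to 239 genes had 0 in 1 replicate and at least 5 FPKM in the other, and 119 to 165 of these were small RNA genes.

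Depth was derived from the deposited bounds, which lie 2 standard deviations around the FPKM and so imply a number of fragments. Protein-coding genes with a single annotated transcript, of at least 1000 bases, and 20 to 200 implied fragments gave 8.79 to 13.0 M fragments per library. The implied fragments assume that the bounds cover counting error alone, which was not tested. Over genes with at least 100 implied fragments, the median difference between replicates was 0.0731 to 0.103 on the log2 scale. Counting error derived in this way gave 0.0721 to 0.0746.

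The 12 libraries of days 4, 5 and 10 were fitted with a cell means model of 6 groups in limma 3.58.1 under R 4.3.3, on log2(FPKM + 1) with an intensity trend of the variance. Each gene was fitted on the libraries that list it, with at least 2 residual degrees of freedom, and the variances were moderated with 1.15 prior degrees of freedom. Adjusted p-values follow Benjamini and Hochberg over all genes of a contrast, two-sided, and a gene was called when its adjusted p was under 0.05. The contrasts were the Cdk9-DN effect at days 4, 5 and 10, their mean, the day 10 effect minus the day 4 effect, and the changes between days within each vector. The 2 single libraries of day 3 were kept out of the fit and their contrast was not tested, a choice made before the data were examined. Their log2 differences were set against 10000 random lists of the same size, matched on mean expression in 20 bins. Tables were handled with Python 3.11.15 and pandas 2.3.3.

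The analysis used 26 gene lists. Their tests followed limma's camera on the moderated statistics with a preset correlation of 0.01, for lists with at least 5 tested members, adjusted over the lists of a contrast. Each test was repeated with a correlation estimated from the list's members, where at least 3 of them were listed in all 12 libraries, and limma's fry was run on these members. Among the lists tested, only the epithelial, pluripotency, immediate early, interferon and histone lists had such an estimate. The other lists kept the preset, so their calls had no such check. The negative estimates of the epithelial, pluripotency and interferon lists were set to 0.001, which is laxer than the preset. Counts per list are given over all genes tested and adjusted over the list alone. The lists, the contrasts, the thresholds and the rule for named genes were fixed before the data were examined.

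Named genes were chosen by a rule. For the averaged effect they were the 12 highest and 12 lowest called genes whose Cdk9-DN libraries all lay on the same side of the control libraries of their day, with a group mean of at least 5 FPKM. For each single day the 5 highest and 5 lowest were taken, and for the change in control cells and for the difference between days the 10 highest and 10 lowest, without the overlap rule for the difference. To these came 16 genes named in advance and up to 4 called members of each list, or up to 2 with the highest mean where none was called. Symbols of unnamed gene models were passed over. Genes outside the rule are said to have been chosen after their values were seen.

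The procedure was tested on simulated data built on the 5343 genes of the averaged effect. For the averaged effect it recovered 67.2%, 86.6% and 81.8% of the genes given log2 differences of 0.5, 1 and 2, and called 4 unchanged genes. For the day 10 effect, also over 5343 genes, it recovered 25.4%, 65.7% and 74.2%, and called 8 unchanged genes.

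The alternatives tried were pseudocounts of 0.1 and 5, no filter on low values or one at 5 FPKM, median-of-ratios scaling, quantile normalization, no variance trend, a separate fit for each day, a minimum log2 difference of 1, inclusion of the day 3 pair, leaving out each day or each library, and a replicate block. Chosen after seeing the data were restrictions to genes listed in all 12 libraries, to protein-coding genes or to a mean of at least 10 implied fragments, values of exactly 0 as no value, and the genes of the within-day block fitted without the block. A group with 1 library, where the other was left out or does not list the gene, is assumed to vary like the other groups. Some genes, 1 of them named by the rule with a call that turned without day 10, are not reported here, and the counts of alternatives for named genes leave them out.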

Results

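Gene expression was followed by RNA sequencing in mouse embryonic fibroblasts of strain OG2/129SV on their way to pluripotency. The cells carried Oct4, Sox2, Klf4 and c-Myc and in addition a control vector or Cdk9-DN, by its name a dominant-negative form of Cdk9. Cdk9 is the kinase of P-TEFb, which releases paused RNA polymerase II into elongation. The cells were collected 3, 4, 5 and 10 days after infection and kept in embryonic stem cell medium with LIF. There were 14 libraries in 8 groups: 2 per vector at days 4, 5 and 10, and 1 per vector at day 3. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these libraries. Values are FPKM as mean ± SD (SD, n = 2), differences are log2 differences of Cdk9-DN minus control unless stated, and p-values are from limma. Where 1 library of a group lists a gene, its p-value takes the spread from the other groups.

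Depth, derived from the deposited bounds, was 11.5 M fragments for the control and 13.0 M for the Cdk9-DN library of day 3. It was 9.75 and 12.1 M (control) and 10.2 and 11.9 M (Cdk9-DN) at day 4, 12.01 and 8.79 M and 10.2 and 12.4 M at day 5, and 11.4 and 11.98 M and 12.7 and 12.95 M at day 10. Each library had 4947 to 5292 genes at 1 FPKM or more. The 10 highest genes held 33.4% to 66.1% of the summed FPKM, and 76.1% in control replicate 2 of day 5. Of 26962 genes listed in any library, 18914 were listed in all 14, and 7460 passed the expression filter. Genes with many exons were listed less often: 51.5% of 1331 protein-coding genes with 1 exon were listed in all 14 libraries, and 5.3% of 3491 with 17 or more exons. The testable genes included 2328 protein-coding genes, 1420 processed pseudogenes, 187 snoRNA, 145 miRNA and 118 snRNA genes, so every count below concerns the genes listed.

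Whether Cdk9 itself moved was not checked. Cdk9 was listed under this symbol in 0 libraries, as were Ccnt1, Pou5f1, Klf4, Cdh1, Alpl and Cdkn1a, so these genes were not analysed here. Hexim1, which encodes an inhibitor of P-TEFb (chromosome 11, 102977639 to 102981039), was lower with Cdk9-DN averaged over days 4, 5 and 10 (-0.49, SE 0.0544, adjusted p = 0.00514). Control and Cdk9-DN stood at 15.4 (1 library) and 10.5 ± 0.0457 FPKM at day 4, 16.1 ± 0.97 and 9.23 ± 0.342 FPKM at day 5, and 13.5 ± 1.64 and 11.4 ± 0.339 FPKM at day 10. The single libraries of day 3 had 17.4 and 10.9 FPKM. On no single day did Hexim1 pass (adjusted p = 0.414, 0.0606 and 0.108 at days 4, 5 and 10), and the call of Hexim1, Cdk9-DN effect averaged over days, ended with the day 3 pair (adjusted p = 0.0806), without day 5 (0.0626) or without day 10 (0.0628). Sox2 stood at 370 ± 4.67 and 314 ± 32.6 FPKM at day 4, and Myc at 831 ± 17.2 FPKM in control cells and 778 FPKM (1 library) at day 5, with transduced and endogenous transcripts not separated. Fut4 stayed below the filter, at 0.0804 to 0.344 FPKM.

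The first comparison, control vector day 10 against day 4, asked what reprogramming did in control cells. By day 10 the cells had shed much of their fibroblast program and had taken up an epithelial one. Among the list members tested, pluripotency genes rose, and genes of DNA replication and mitosis fell. Genes of the interferon response rose as well, as did the keratinocyte and trophoblast markers tested. The members tested were a small part of some lists. Of 30 S phase genes 8 were listed and 6 tested here, and of 30 mitosis genes 10 were listed and 5 tested. Of 35 epithelial genes 12 were tested. Of 5814 genes tested, 2907 were called, 1639 higher and 1268 lower at day 10, and 3211 had an unadjusted p under 0.05. The split between higher and lower depends on scaling: it was 1409 and 1526 under median-of-ratios scaling and 1204 and 1606 under quantile normalization.

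Epithelial genes were higher at day 10 in control cells, 11 of 12 tested, with 0 lower (median 4.54, adjusted p = 1.39e-08). Cldn4, a tight junction claudin, was listed at 0 in both day 4 libraries and at 102 and 98.0 FPKM at day 10 (adjusted p = 8.89e-09). Krt18, a keratin of simple epithelia, rose from 0.591 ± 0.232 to 85.2 ± 1.96 FPKM (log2 change 5.77, adjusted p = 2.27e-07). Krt8, its partner keratin, rose with it (4.56, adjusted p = 1.30e-06), and the P-cadherin gene Cdh3 did not pass (0.16, adjusted p = 0.302). Pluripotency genes were higher in 12 of 13 (median 2.35, adjusted p = 4.83e-06). Nanog went from 0.893 ± 0.264 FPKM to 11.5 FPKM (1 library; log2 change 2.73, adjusted p = 1.95e-04), and Klf2 did not pass (-0.18, adjusted p = 0.535). Among the strongest single risers were the peptide hormone genes Trh, from 0.993 ± 0.43 to 176 ± 18.5 FPKM (6.48, SE 0.188, adjusted p = 5.47e-07), and Npy, listed at 0 in both day 4 libraries and at 134 and 123 FPKM at day 10.

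Mesenchymal regulators and contractile genes were lower at day 10 in all 11 tested (median -2.09, adjusted p = 1.09e-06). N-cadherin (Cdh2) fell from 34.1 ± 0.374 to 2.56 ± 0.0204 FPKM (-3.31), Snai2 from 6.77 ± 0.0671 to 0.594 ± 0.0315 FPKM (-2.29, adjusted p = 7.42e-06) and Snai1 from 17.04 ± 1.04 to 9.42 ± 0.579 FPKM (-0.79, adjusted p = 0.00213). Fibroblast matrix genes were lower in 7 of 8 (median -0.75, adjusted p = 0.00191). Decorin (Dcn) fell from 15.6 ± 0.642 to 4.07 ± 0.49 FPKM (-1.71, adjusted p = 2.72e-05), while the gelatinase gene Mmp2 was the 1 higher (0.45, adjusted p = 0.0119). Thy1, a fibroblast surface marker, went from 82.8 ± 1.23 to 16.3 FPKM (1 library; -2.27, adjusted p = 6.82e-06). The Wnt modulator Sfrp2 was among the strongest fallers, from 93.6 ± 11.6 to 5.32 ± 0.0909 FPKM (-3.90, SE 0.117, adjusted p = 6.25e-07), as was the protocadherin Pcdh10 (-3.64, adjusted p = 2.53e-05).

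S phase genes were lower at day 10 in control cells in all 6 tested (median -1.10, adjusted p = 2.04e-04), among them the replication helicase gene Mcm2, from 48.5 ± 1.67 to 19.1 ± 0.218 FPKM (-1.30). Mitosis genes were lower in all 5 (median -1.21, adjusted p = 0.00243), with Plk1 at -1.25 and Birc5 at -1.21. Interferon response genes were higher in 5 of 6 (median 1.46, adjusted p = 0.0112). Bst2, which tethers virions, went from 24.4 ± 1.92 to 215 FPKM (1 library; 3.09), and Isg15 did not pass (0.56, adjusted p = 0.105). Keratinocyte and trophoblast markers were higher in all 5 (median 1.56, adjusted p = 0.00122), with Sfn rising from 6.13 ± 0.115 to 71.5 ± 4.82 FPKM (3.34). Immediate early genes were higher in 13 and lower in 4 of 19 (adjusted p = 0.0201), and adjusted p = 0.307 with an estimated correlation. Histone genes were lower in 11 and higher in 2 of 29 (adjusted p = 0.00243), and adjusted p = 0.234 with an estimated correlation. TGF-beta response genes did not pass (adjusted p = 0.783), with a median of 0.16 and a mean of -0.06, nor did p53 targets (adjusted p = 0.402; median -0.08, mean 0.09).

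The comparison of control vector day 5 against day 4 asked how control cells start this course. They lost TGF-beta and immediate early transcripts and gained replication transcripts, the reverse of the later course for S phase genes. Of 5951 genes tested, 299 were called, 109 higher and 190 lower, with 1206 unadjusted. TGF-beta response genes were lower in 5 of 6 (median -0.79, adjusted p = 5.12e-09). Ctgf, a matricellular growth factor gene, fell from 173 ± 0.629 to 76.8 ± 2.55 FPKM (-1.16, adjusted p = 5.29e-05). Immediate early genes were lower in 9 and higher in 1 of 18 (median -0.44, adjusted p = 5.25e-07, and 0.0204 with an estimated correlation), and S phase genes higher in 2 of 6, or 6 adjusted over the list alone (median 0.34, adjusted p = 1.03e-04). Mesenchymal genes (3 of 10 lower, adjusted p = 2.14e-04), p53 targets (2 of 6 lower, 7.12e-05), heat shock genes (1 of 11 lower, 2.14e-04), senescence genes (3 of 11 lower, 0.00295) and keratinocyte and trophoblast markers (1 of 8 lower, 0.0441; 0.0549 and 0.0621 under median-of-ratios scaling and quantile normalization) also passed, and ribosome biogenesis and Myc target genes passed upward (2 of 5 higher, 0.00155). Pluripotency genes (2 of 15 higher) gave adjusted p = 0.0567, and 0.0407 with the estimated correlation, which was set to a value laxer than the preset. This list gave 0.0303 under median-of-ratios scaling and 0.00948 under quantile normalization. The count was 43 without control replicate 1 of day 4, 86 without its replicate 2, 125 without control replicate 1 of day 5 and 68 without its replicate 2, and under quantile normalization 65 were higher and 232 lower.

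For the Cdk9-DN effect at day 10, the question was how Cdk9-DN changed the state the cells had reached. Cdk9-DN cells had less of the epithelial program and lower levels of most immediate early, TGF-beta response and several pluripotency genes. They had more transcripts of the few S phase genes tested. Several matrix and mesenchymal genes that control cells had reduced stood higher, some stood lower still, and neither list passed. Of 5740 genes tested, 1658 were called, 834 higher and 824 lower with Cdk9-DN, and 2297 had an unadjusted p under 0.05. The count was 1033 without control replicate 1, 976 without Cdk9-DN replicate 1 and 1018 without Cdk9-DN replicate 2 of day 10, and 405 in a separate fit for each day.

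Epithelial genes were lower with Cdk9-DN at day 10 in all 12 tested (median -1.46, adjusted p = 8.65e-11). Krt18 (chromosome 15, 101858647 to 101862457) stood at 85.2 ± 1.96 FPKM in control and 6.71 ± 0.552 FPKM in Cdk9-DN cells (-3.49, SE 0.131, adjusted p = 8.33e-06). Cldn6, a claudin of early embryonic epithelia, stood at 24.8 (1 library) and 3.31 ± 0.388 FPKM (-2.58, adjusted p = 4.03e-05). Cldn4 had 102 and 98.0 FPKM in control and 29.0 and 27.3 FPKM in Cdk9-DN libraries (-1.79, SE 0.0726, adjusted p = 1.30e-05). Cldn3 stood at 81.1 ± 1.24 and 27.0 ± 2.98 FPKM (-1.56, adjusted p = 0.00122).

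**Figure D1:**
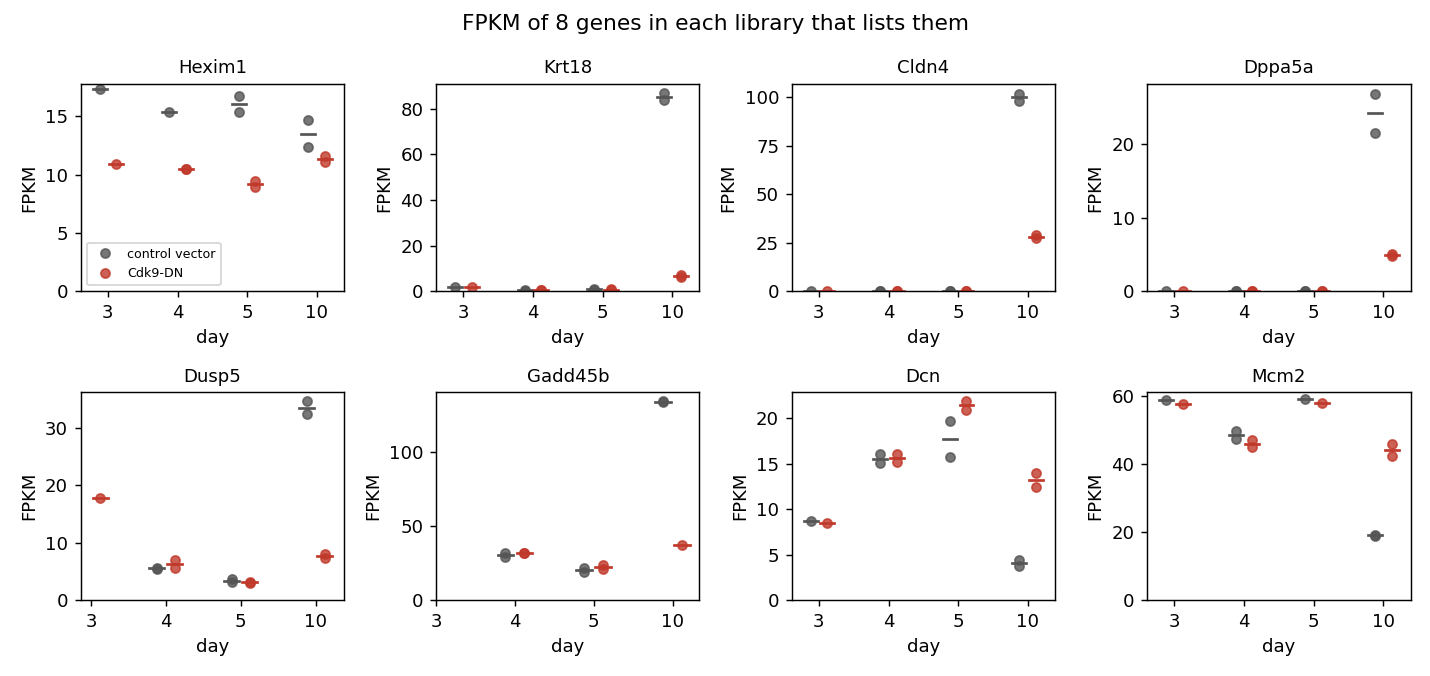
FPKM in each library of Hexim1, Krt18, Cldn4, Dppa5a, Dusp5, Gadd45b, Dcn and Mcm2 by day after infection, with control in grey, Cdk9-DN in red and bars at the means. At day 10 Krt18 stood at 85.2 ± 1.96 FPKM in control and 6.71 ± 0.552 FPKM in Cdk9-DN cells.

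Pluripotency genes were lower with Cdk9-DN at day 10 in 7 of 13 and higher in 1, with 5 not passing, and 9 lower and 3 higher adjusted over the list alone (median -0.62). The list test gave adjusted p = 0.0514. It gave adjusted p = 0.0464 with the estimated correlation, which was negative and set to 0.001, a laxer value than the preset. Dppa5a (chromosome 9, 78214859 to 78215984), an RNA-binding protein of pluripotent cells, stood at 24.1 ± 3.79 and 4.92 ± 0.201 FPKM (-2.08, SE 0.114, adjusted p = 4.87e-05). Utf1, a chromatin protein of stem cells, stood at 11.8 ± 1.52 and 5.53 ± 0.549 FPKM (-0.97, adjusted p = 0.00500). Sox15 stood at 19.0 ± 0.657 and 8.83 ± 3.12 FPKM (-1.06, adjusted p = 0.0210), and Nr0b1 was the 1 higher, at 4.10 ± 0.27 and 10.9 ± 0.679 FPKM (1.22, adjusted p = 1.65e-04). Nanog, with 11.5 and 6.24 FPKM in 1 library each, did not pass (-0.79, adjusted p = 0.0503). In 1 Cdk9-DN library of day 10 the epithelial surface gene Epcam had 55.9 FPKM, and it was not listed in the others of that day.

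Immediate early genes were lower with Cdk9-DN at day 10 in 14 of 18 and higher in 1 (median -0.60, adjusted p = 2.02e-06, and 0.0464 with an estimated correlation). Adjusted over the list alone, 15 were lower and 1 higher. The MAP kinase phosphatase gene Dusp5 (chromosome 19, 53603599 to 53616921) stood at 33.5 ± 1.59 and 7.72 ± 0.442 FPKM (-1.98, SE 0.107, adjusted p = 4.58e-05). Gadd45b, a stress sensor (chromosome 10, 80392836 to 80394949), stood at 134 ± 0.638 and 37.4 FPKM (1 library; -1.82, adjusted p = 1.65e-04). Egr1 was the 1 higher, at 12.8 ± 0.497 and 18.1 ± 0.559 FPKM (0.47, adjusted p = 0.00232). TGF-beta response genes were lower in 6 of 7 (median -0.92, adjusted p = 9.81e-05). Ctgf stood at 376 (1 library) and 195 ± 2.18 FPKM (-0.95, adjusted p = 8.44e-05), and Tgfbi did not pass (0.29, adjusted p = 0.197).

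S phase genes were higher with Cdk9-DN at day 10 in all 5 tested (median 0.85, adjusted p = 4.01e-05). Mcm2 (chromosome 6, 88833469 to 88848774) stood at 19.1 ± 0.218 and 44.0 ± 2.53 FPKM (1.16, SE 0.0566, adjusted p = 2.39e-04), and Mcm4 at 15.5 ± 0.309 and 28.6 ± 0.611 FPKM. Replication-dependent histone genes were higher in 16 of 28, or 19 adjusted over the list alone (median 0.66, adjusted p = 3.72e-07), and adjusted p = 0.0503 with an estimated correlation. Hist1h4i stood at 8.75 ± 0.383 and 17.8 ± 0.374 FPKM (0.95, adjusted p = 0.00306), and reads of near-identical histone copies were not separated. Of the mitosis genes only Birc5 passed (0.48, adjusted p = 0.0148; list adjusted p = 0.259). The ribosome biogenesis and Myc target genes were too few for a list test, and the 3 tested were higher: Rrs1 at 19.3 ± 0.717 and 44.7 ± 0.633 FPKM (1.17, adjusted p = 7.58e-06), Ddx21 (0.94) and Nip7 (0.72).

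Fibroblast matrix genes were higher in 3 and lower in 2 of 8, and their list test did not pass (adjusted p = 0.301). Dcn (chromosome 10, 96942245 to 96980777) stood at 4.07 ± 0.49 and 13.2 ± 1.09 FPKM (1.49, SE 0.116, adjusted p = 2.16e-04), and Mmp2 at 74.8 (1 library) and 51.3 ± 1.92 FPKM (-0.54). Mesenchymal genes were higher in 4 and lower in 2 of 11 (adjusted p = 0.301), with Twist1 at 12.5 ± 1.25 and 22.9 ± 1.01 FPKM (0.83) and Tgfb3 at 10.1 ± 0.551 and 5.14 ± 0.218 FPKM (-0.86). Senescence genes were higher in 3 and lower in 5 of 11 (adjusted p = 0.713; median 0.04, mean -0.07), among them the chemokine Ccl2 at 11.7 ± 0.137 and 25.2 ± 0.643 FPKM and the cell cycle inhibitor Cdkn1b at 45.1 ± 1.58 and 22.3 ± 0.688 FPKM. Targets of p53 were higher in 1 and lower in 3 of 7 (adjusted p = 0.211), with Gdf15 at 6.18 ± 0.466 and 1.61 ± 0.315 FPKM. Heat shock genes were lower in 5 of 10 (adjusted p = 0.0903) and interferon genes in 2 of 5 (0.269), oxidative phosphorylation genes were higher in 3 of 12 (0.259), and neural markers were higher in 3 and lower in 1 of 5 (0.0973). Pausing and elongation factors were higher in 2 and lower in 1 of 6 (0.479). Leo1 of the PAF complex stood at 14.1 ± 0.765 and 19.7 ± 1.62 FPKM (0.46, adjusted p = 0.00741), and Ell2 of the super elongation complex at 10.3 ± 1.67 and 5.84 FPKM (1 library; -0.72, adjusted p = 0.0157).

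Some lists had too few tested members for a list test at day 10, and their genes are given singly. Of 4 keratinocyte and trophoblast markers 2 were lower, Sfn at 71.5 ± 4.82 and 36.9 ± 0.983 FPKM (-0.94, adjusted p = 3.27e-04) and Krt4 (-0.77, adjusted p = 6.95e-04), while Krt5 did not pass (0.22, adjusted p = 0.514). Of 2 endothelial markers the claudin Cldn5 was lower, with 3.77 and 3.60 FPKM in control and 0.92 and 0.956 FPKM in Cdk9-DN libraries (-1.27). The laminin gene Lama1 was higher among 2 endoderm and mesoderm markers, at 1.16 ± 0.237 and 2.29 FPKM (1 library; 0.61, adjusted p = 0.0461), and Gata6 did not pass (-0.15, adjusted p = 0.325). Of 2 glycolysis genes Pgam1 was higher (0.36, adjusted p = 0.00346), and of 3 blood and macrophage markers 0 passed by limma, with 0 unadjusted, Hbb-y standing at 43.3 ± 2.62 and 44.9 ± 3.66 FPKM. Of the reprogramming factors, the methylation genes, the muscle markers and the mitochondrially encoded genes, 0 were testable.

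The largest single differences at day 10 included genes listed at 0 in a whole group, and whether such values of exactly 0 are true zeros or a step of the quantification was not tested. Pde12, a 2'-phosphodiesterase, was listed at 0 in both control libraries and at 9.95 and 10.5 FPKM with Cdk9-DN (adjusted p = 2.03e-06). Prss8, an epithelial serine protease, had 21.8 and 21.9 FPKM in control libraries and 0 in the 1 Cdk9-DN library that lists it (adjusted p = 1.43e-06). Fabp3, a fatty acid carrier, had 32.2 and 30.5 FPKM in control libraries and was listed at 0 in both Cdk9-DN libraries. The microRNA genes Mir221 and Mirlet7c-2 had 55.2 and 52.6 FPKM in control libraries and were listed at 0 with Cdk9-DN. The calls of Fabp3, Mir221 and Mirlet7c-2 ended when single libraries were left out (adjusted p up to 0.151, 0.122 and 0.113).

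At days 4 and 5, the question was whether Cdk9-DN acts early. Few single genes differed, while some gene groups leaned together. At both days TGF-beta response genes leaned higher with Cdk9-DN, opposite to day 10. At day 5 pluripotency genes leaned lower, at low levels in both vectors. At day 4, 2 of 5950 genes were called, both lower (388 unadjusted): the small RNA gene SNORA35, at 17.03 and 13.8 FPKM in control libraries and listed at 0 with Cdk9-DN and at every other day (adjusted p = 5.23e-06), and Dhrs13, a dehydrogenase gene (adjusted p = 0.00438). At day 5, 10 of 5902 genes were called, 4 higher and 6 lower (500 unadjusted). Pvrl2, an adhesion molecule also named nectin-2, was listed at 0 in both control libraries and at 16.8 and 29.3 FPKM with Cdk9-DN (adjusted p = 0.00104). Dhrs13 was lower again (adjusted p = 0.00163), as was a U6 gene on chromosome 10 (66698609 to 66698709), at 39.1 and 53.8 FPKM in control libraries and listed at 0 with Cdk9-DN (adjusted p = 2.42e-06). Ramp3, a receptor modifier, stood at 28.1 ± 0.406 and 20.1 ± 0.821 FPKM (-0.47, SE 0.0551, adjusted p = 0.0367).

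Among the lists, no member was called at day 4 or day 5 by limma over all genes. TGF-beta response genes were higher with Cdk9-DN at day 4 (6 tested, median 0.15, adjusted p = 0.00295, 3 adjusted over the list alone) and at day 5 (7 tested, 6 of them positive, median 0.26, adjusted p = 1.10e-07, 6 adjusted over the list alone). No correlation could be estimated for this list or the keratinocyte, fibroblast matrix, mesenchymal and pausing lists. Their calls rest on the preset correlation. Immediate early genes were higher at day 4 (median 0.07, adjusted p = 0.00295; adjusted p = 0.263 with an estimated correlation) and at day 5 (median 0.13, adjusted p = 0.00746; adjusted p = 0.195 with an estimated correlation). Keratinocyte markers were higher at day 4 (8 tested, median 0.23, adjusted p = 0.00733), with Krt14 at 8.16 ± 0.0217 and 10.6 ± 0.132 FPKM. Fibroblast matrix genes were lower at day 4 (8 tested, median -0.16, adjusted p = 0.0212) and higher at day 5 (7 tested, median 0.16, adjusted p = 0.0273), and mesenchymal genes were higher at day 5 (10 tested, median 0.11, adjusted p = 0.0253). Histone genes were higher at day 5 (28 tested, median 0.24, adjusted p = 5.08e-05; adjusted p = 0.140 with an estimated correlation). Pluripotency genes (15 tested, median -0.13, adjusted p = 0.0132) and pausing factors (7 tested, median -0.12, adjusted p = 0.0345) were lower at day 5. The pluripotency genes tested had group means of at most 3.13 FPKM at day 5 (Trh in control cells), and Nr5a2 and Sox15 stood at 0 with both vectors.

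The limits of the early counts are wide. For the Cdk9-DN effect at day 4 the count was 19 with no low filter, 6 with a pseudocount of 0.1 and 7 in a separate fit. It was 7 and 6 without control replicates 1 and 2 of day 4, 10 and 8 without Cdk9-DN replicates 1 and 2 of day 4, 4 without either day 5 control, 5 without either day 10 control and 1 without either Cdk9-DN replicate of day 5, where the call of Dhrs13, Cdk9-DN effect at day 4, ended (adjusted p = 0.0525 and 0.0522). For the Cdk9-DN effect at day 5 it was 24 with no low filter, 19 without Cdk9-DN replicate 2 of day 5 and 16 without any of the day 4 libraries or control replicate 1 of day 5, and Ramp3 ended without any of 10 libraries (adjusted p up to 0.169). With values of exactly 0 as no value, limma called 0 genes at both days (385 and 466 unadjusted), so the calls of SNORA35, Dhrs13, Pvrl2 and U6 rest on such values.

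The Cdk9-DN effect averaged over days 4, 5 and 10 asked what Cdk9-DN did on average. Averaged, epithelial and pluripotency genes stood lower and histone genes higher, and for the epithelial genes the difference came from day 10. Single genes lower in every Cdk9-DN library included the arginase gene Arg1 and the polarity gene Pard6b. Single genes higher in every one included the proteoglycan gene Gpc4 and the linker histone gene Hist1h1c. Of 5343 genes tested, 585 were called, 226 higher and 359 lower, and 1416 had an unadjusted p under 0.05. The count of genes for the Cdk9-DN effect averaged over days was 22 without day 10, 2 with the day 3 pair, and 326 to 389 without any 1 of the libraries other than control replicates 1 and 2 of day 10.

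By rule, the genes lower in every Cdk9-DN library included Arg1, an arginase, at 40.2 ± 3.57 and 10.4 ± 0.258 FPKM at day 10 (-0.79 averaged, adjusted p = 6.73e-04). Pcsk1n, an inhibitor of prohormone cleavage, stood at 167 ± 5.2 and 98.1 ± 4.58 FPKM at day 10 (-1.01, adjusted p = 0.0107). The polarity gene Pard6b stood at 9.75 ± 0.877 and 3.76 ± 0.409 FPKM (-0.60, adjusted p = 0.00619). Krt8 stood at 7.06 ± 0.182 and 5.35 ± 0.921 FPKM at day 4, 15.6 ± 0.075 and 11.2 ± 0.189 FPKM at day 5, and 189 (1 library) and 98.0 ± 0.228 FPKM at day 10 (-0.58, adjusted p = 0.00375). Dhrs13 (chromosome 11, 77845782 to 77851368) had 11.9, 11.2, 9.22, 12.6 and 10.6 FPKM in the control libraries of days 4 to 10 that list it, 9.01 FPKM in that of day 3, and was listed at 0 in all 5 Cdk9-DN libraries that list it, with the same doubt about values of exactly 0. Also lower were Rtn2 (-0.72), Aplp1 (-0.65), Atp12a (-0.62), Pcbd1 (-0.60), Tubb4a (-0.59) and Plac8 (-0.59).

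Genes higher in every Cdk9-DN library included the heparan sulfate proteoglycan Gpc4, at 33.0 ± 0.862 and 58.0 ± 0.125 FPKM at day 10 (0.35, adjusted p = 6.42e-04), and the endothelin receptor Ednrb, at 2.09 ± 0.0667 and 5.13 ± 1.22 FPKM at day 5 (0.59, adjusted p = 0.00530). The methyltransferase gene Lcmt2 stood at 2.84 ± 0.0834 and 6.74 ± 0.101 FPKM at day 10 (0.53, adjusted p = 0.00226). The linker histone gene Hist1h1c stood at 39.9 ± 1.55 and 51.4 ± 4.11 FPKM at day 4 and at 31.0 ± 0.486 and 44.3 ± 0.694 FPKM at day 5 (0.30, adjusted p = 0.00716). Also higher were Gnai1 (0.53), Antxr2 (0.51), the Wnt inhibitor Dkk2 (0.47), Hist1h4n (0.42), Prkcdbp (0.40), Hist1h1e (0.33) and Hist1h2bc (0.30).

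Of 14 lists tested on the averaged effect, 5 passed. Epithelial genes were lower in 10 of 12, or 12 adjusted over the list alone (median -0.50, adjusted p = 3.02e-11), though the list did not pass at day 4 (adjusted p = 0.707) or day 5 (0.838). Pluripotency genes were lower in 4 of 13, or 7 lower and 1 higher over the list alone (median -0.28, adjusted p = 0.00652). Histone genes were higher in 4 of 27, or 11 over the list alone (median 0.28, adjusted p = 1.42e-08, and 0.0423 with an estimated correlation), and did not pass at day 4 (adjusted p = 0.542). Immediate early genes were lower in 5 of 17 (median -0.11, adjusted p = 0.00200), and adjusted p = 0.168 with an estimated correlation. TGF-beta response genes were lower in 2 of 6, or 3 over the list alone (median -0.13, adjusted p = 0.0425). Their correlation could not be estimated, and adjusted p = 0.0531 arose only through the adjustment, when other lists took their estimates. Without day 10 the immediate early and TGF-beta lists turned upward (medians 0.10 and 0.21), and the list epithelial genes, averaged effect, did not pass (median -0.01, adjusted p = 0.677). The TGF-beta call ended without control replicate 1 or 2 of day 4 (adjusted p = 0.0516 and 0.0639), control replicate 1 of day 5 (0.0825), Cdk9-DN replicate 1 of day 5 (0.0542) or Cdk9-DN replicate 2 of day 10 (0.118), and the pluripotency call without day 5 (0.108). Quantile normalization ended the TGF-beta call as well (adjusted p = 0.0931). Not passing were pausing factors (adjusted p = 0.980; mean -0.06), p53 targets (0.533; median 0.03, mean -0.09), fibroblast matrix (0.438), mesenchymal (0.385), senescence (0.953), interferon (0.155), oxidative phosphorylation (0.195), heat shock (0.195) and neural genes (0.155). The fibroblast markers Thy1 (0.02, adjusted p = 0.702), Snai1 (-0.10, adjusted p = 0.445) and Snai2 (0.14, adjusted p = 0.192) did not pass.

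**Figure D2:**
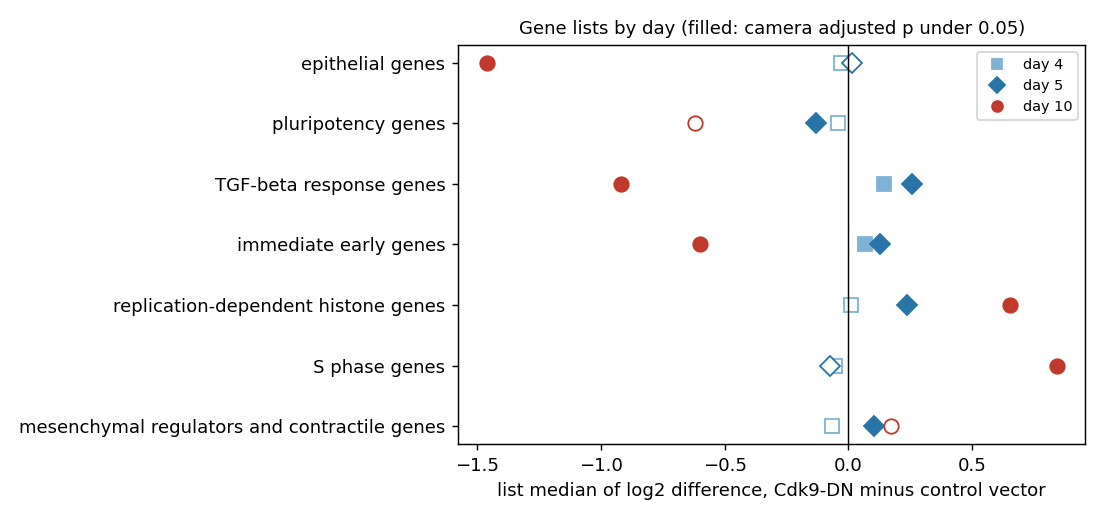
Median log2 difference of Cdk9-DN minus control for 7 gene lists at days 4, 5 and 10, filled where the list test passed. Epithelial genes had a median of -1.46 at day 10, and TGF-beta response genes 0.26 at day 5 and -0.92 at day 10.

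At day 3 each vector had 1 library, and the differences were not tested and are only described. Most gene groups lay within what random lists gave. Immediate early genes and keratinocyte markers lay at the high end of the random lists. Of 5659 genes listed in both libraries and passing the filter, 189 were higher and 181 lower by at least 1. Immediate early genes were higher in 11 of 12 (median 0.09, percentile 98.2 of 10000 random lists), and keratinocyte and trophoblast markers in 4 of 6 (percentile 99.3). The other 13 lists lay at percentiles 12.6 to 88.6. Random genes were drawn independently, so these percentiles leave out correlation within a list, which was estimated at 0.24 for the immediate early genes. The genes called for the averaged effect had the same sign at day 3 in 51.3% of 509, and those called at day 10 in 46.1% of 1393.

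The last comparison asked how Cdk9-DN changed the course from day 4 to day 10. At the median, genes picked for a change in control cells changed less with Cdk9-DN. Most of the rising genes and a smaller share of the falling genes were called in the same direction. The epithelial rise was smaller, and the mesenchymal decline took place in both. Some genes and gene groups differed between the vectors in their change from day 4 to day 10. Among them were the TGF-beta response genes and the transcription factor genes Foxd1 and Insm1. The TGF-beta gene Ctgf first fell to day 5 with both vectors, to 76.8 FPKM in control and 92.0 FPKM in Cdk9-DN cells. For Cdk9-DN day 10 against day 4, 2208 of 5816 genes were called, 1423 higher and 785 lower (1043 and 1121 under median-of-ratios scaling, 898 and 1087 under quantile normalization). Epithelial genes were higher in 11 of 13 (median 2.17, adjusted p = 5.18e-07), pluripotency genes higher in 11 of 14 (median 1.76, adjusted p = 2.05e-06), and mesenchymal genes lower in all 10 (adjusted p = 2.52e-07). Keratinocyte markers were higher in all 5 (adjusted p = 2.92e-04), mitosis genes lower in all 5 (4.62e-04) and fibroblast matrix genes lower in 5 of 8 (0.00555). TGF-beta response genes were lower in 4 and higher in 2 of 7 (median -0.51, adjusted p = 0.0323), p53 targets lower in 4 and higher in 1 of 6 (median -0.56, adjusted p = 0.0168) and heat shock genes lower in 2 of 10 (median -0.28, adjusted p = 0.0106), lists that did not pass in control cells (medians 0.16, -0.08 and 0.36; adjusted p = 0.783, 0.402 and 0.604). Of these, only the TGF-beta list passed on the difference between vectors (adjusted p = 1.24e-04, against 0.441 for p53 targets and 0.0717 for heat shock genes). Senescence genes were lower in 6 and higher in 2 of 11 (adjusted p = 0.00593), pausing factors lower in 3 of 6 (0.0367; 0.0654 under quantile normalization) and interferon genes higher in 4 of 5 (0.0226).

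Across the 2749 genes called in control cells and measured in both, the median ratio of the Cdk9-DN change to the control change was 0.574, with 0.582 and 0.590 in the single Cdk9-DN replicates. Genes are not independent replicates. Because the genes were picked for their change in control cells, a ratio below 1 is partly built in. Picking them in a separate control replicate does not remove this, and the reverse, genes picked with Cdk9-DN, was not measured. The ratio was 0.633 for 1565 rising genes and 0.485 for 1184 falling genes, and when genes were picked in replicate 1 and measured in replicate 2 it was 0.585 (960 genes), or 0.557 (909 genes) the other way round. For these picked genes the ratios of medians, taken for each Cdk9-DN replicate, were 0.642 to 0.746 for rising and 0.556 to 0.662 for falling genes. Of the 1565 risers, 1034 were also called higher at day 10 with Cdk9-DN and 27 were called lower. Of the 1184 fallers, 576 were also called lower and 39 were called higher. The remaining genes were not called with Cdk9-DN, which does not mean that they stayed unchanged.

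**Figure D3:**
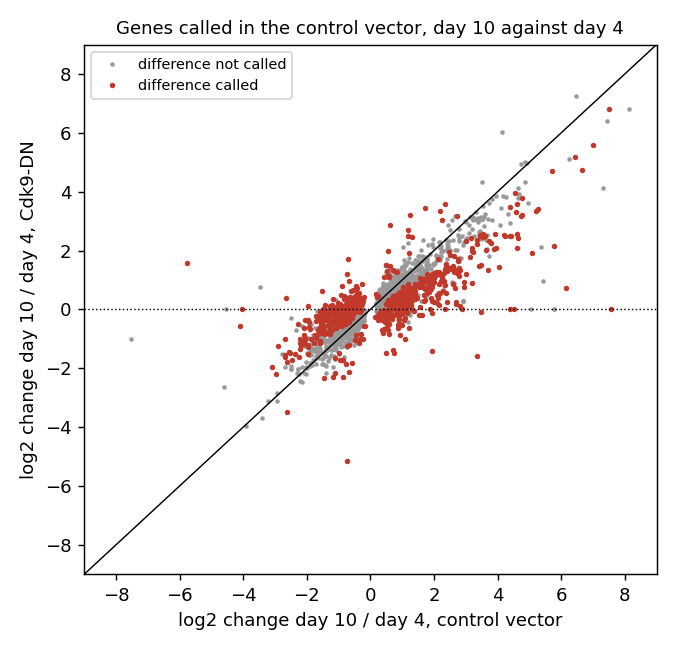
Log2 change from day 4 to day 10 with Cdk9-DN against that in control cells, for genes called in control cells, with the identity line and genes whose change differed between vectors in red. The median ratio was 0.574.

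The difference of the Cdk9-DN effect between day 10 and day 4 was called in 869 of 5523 genes, 439 higher and 430 lower, with 1729 unadjusted. It was 550 without control replicate 2 of day 4, 547 without Cdk9-DN replicate 1 of day 4 and 549 without Cdk9-DN replicate 1 of day 10. Epithelial genes were lower in 10 of 12, TGF-beta response genes in 5 of 6, and immediate early genes in 11 of 18 with 1 higher. Histone genes were higher in 6 of 28, and the list gave adjusted p = 0.133 with an estimated correlation. Krt18 had a difference of -3.60 (SE 0.185), and Atp1b1, a subunit of the sodium pump, stood at 16.8 and 17.5 FPKM in control and 2.16 and 2.59 FPKM in Cdk9-DN libraries at day 10 (-2.69). Foxd1, a forkhead factor (chromosome 13, 99124200 to 99126660), stood at 15.3 ± 2.9 and 10.3 ± 0.785 FPKM at day 4 and 22.4 ± 7.58 and 136 ± 3.52 FPKM at day 10 (3.10, SE 0.319, adjusted p = 0.00238). The neurofilament gene Nefl stood at 3.78 ± 0.0651 and 3.43 ± 0.0223 FPKM at day 4 and 1.91 ± 0.158 and 13.4 ± 0.158 FPKM at day 10 (2.42), and the neuroendocrine factor Insm1 at 0.944 ± 0.111 and 5.33 ± 0.299 FPKM at day 10 (1.94). Lrr1 stood at 5.9 ± 1.17 and 18.8 ± 0.351 FPKM at day 10 (2.08) and the milk protein gene Csn1s1 at 5.03 ± 0.83 and 18.2 ± 0.324 FPKM (1.95). Pluripotency genes did not pass on this difference (adjusted p = 0.162), nor did fibroblast matrix genes (0.121), neural markers (0.203), pausing factors (0.401), interferon genes (0.401) or the mesenchymal, senescence and oxidative phosphorylation genes (0.441 each).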

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

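The tests of other splits of the libraries, of the correlation over all genes and of the left-out day 5 control library were planned. The tests of scaling, of values listed at 0, of cultures, of S phase genes and of the direction among called genes were chosen only after the results were seen.

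The Cdk9-DN effect differed between day 10 and day 4 in 869 genes, by limma's test of the difference itself, and this test picked out the lists and genes of this and the next paragraph. Among the gene lists, the difference passed for epithelial genes (adjusted p = 3.06e-11) and TGF-beta response genes (adjusted p = 1.24e-04). It also passed for immediate early genes (adjusted p = 6.41e-07, and adjusted p = 0.0473 with an estimated correlation). For replication-dependent histone genes it passed with the preset correlation (adjusted p = 5.63e-05) and gave adjusted p = 0.133 with an estimated correlation.

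Protein-coding genes with a higher effect at day 10 were Pde12 (adjusted p = 1.26e-05), Nefl (4.11e-05), Insm1 (0.00132), Klk14 (0.00222), Foxd1 (0.00238), Csn1s1 (0.00238), Lrr1 (0.00417) and Clec3b (0.0125). Protein-coding genes with a lower effect were Prss8 (adjusted p = 9.50e-06), Krt18 (6.94e-05), Alox15 (6.94e-05) and Atp1b1 (0.00391). Small RNA genes with a higher effect were SNORA35 (adjusted p = 9.50e-06) and Snora2b (0.0151). Those with a lower effect were U1 (9.50e-06), SNORA61 (4.38e-04), SNORA55 (0.00951), SNORA41 (0.0290), SNORD58 (0.0358) and SNORD113 (0.0448), each listed at 0 in at least 1 group or library.

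The averaged effect called 585 genes, and 3 of 100 splits of the libraries within days, the real one included, called as many, the highest other being 632. That share lies under the bound set in advance. The count follows day 10, however: the 32 other splits that kept the day 10 libraries apart by vector called 293 to 632 genes, and the 67 that mixed them called 8 to 18. The share therefore cannot decide whether an effect averaged over days goes beyond chance. Nor can it decide on differences between cultures, which replicates might share.

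The Cdk9-DN effect at day 10 was called for 1658 genes, that at day 5 for 10 and that at day 4 for 2. Scaling and values listed at 0 are argued against as the whole cause: 1458 genes were called at day 10 under the lower of 2 scalings, 1390 of them among the 1658, and 1633 with values of exactly 0 as no value, 1538 of them among the 1658. Whether part of the control's change from day 4 to day 10 is missing with Cdk9-DN over all tested genes stays open: across genes, which are not independent replicates, its correlation with the day 10 effect from different control replicates was -0.161 by Pearson, short of the bound set in advance, and -0.401 by Spearman, past it, and the bound named neither kind. Among the 1332 genes called at day 10 that could be followed, 86.6% differed opposite to the control's change, which decides nothing, because both values hold the control cells of day 10 with opposite sign and the genes were picked on that difference. A difference between cultures stays open and cannot be told apart from the vector. Replicates differed by at most 1.43 times the counting error derived from the bounds and might share a culture.

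The TGF-beta response genes were higher with Cdk9-DN at days 4 and 5 and lower at day 10. The difference between days 10 and 4 passed its test (adjusted p = 1.24e-04), and that between days 10 and 5 was not tested. These list tests rest on the preset correlation, as none could be estimated for this list. Control replicate 2 of day 5, in which few genes took most of the summed FPKM, is argued against as the source: the day 5 median was 0.26 with it and 0.23 without it (0.2295 unrounded). A culture difference stays open here as for day 10 (largest ratio 1.43), and beyond the vector no biological explanation was tested.

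Replication-dependent histone genes were higher with Cdk9-DN at days 5 and 10 with the preset correlation, and did not pass with an estimated correlation (adjusted p = 0.140 and 0.0503). More S phase transcripts are argued against at day 5, where the S phase genes had a median of -0.0733 and the histone genes of 0.238. At day 10 the medians were 0.845 and 0.655, which is consistent with the hypothesis of a larger share of cells in S phase at that day, formed and tested on the same data. Reads shared between near-identical histone copies were not tested and stay open at both days.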

How the results depend on the processing

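The tests on genes listed in all 12 libraries, on protein-coding genes, on values of exactly 0 as no value, on a mean of at least 10 implied fragments and on the genes of the within-day block without the block were chosen after the results were seen. Of the counts and the ratio under all alternatives, 188 stayed within 1.5 times or within the spread and 85 moved. List calls stayed in 340 cases, ended in 17 and turned in 2. Calls of named genes reported here stayed in 2763 cases, ended in 504, arose in 8 and turned in 15.

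With fewer genes tested, most counts fell. Genes listed in all 12 libraries gave 244 for the Cdk9-DN effect averaged over days, 1 for the Cdk9-DN effect at day 4, 3 for the Cdk9-DN effect at day 5, 768 for the Cdk9-DN effect at day 10 and 396 for the difference of the Cdk9-DN effect between day 10 and day 4. They gave 1498 for control vector day 10 against day 4, 86 for control vector day 5 against day 4 and 1141 for Cdk9-DN day 10 against day 4. Protein-coding genes gave 4 at day 4, 1799 for control day 10 against day 4 and 1451 with Cdk9-DN. A minimum log2 difference of 1, which can only lower a count, left 22 averaged, 318 at day 10, 303 for the difference, 975 and 51 for the control changes to days 10 and 5, and 666 with Cdk9-DN. For the rise to 4 at day 4 among protein-coding genes and for the other alternatives the cause was not tested. Day 4 gave 6 genes with a pseudocount of 0.1, 19 with no low filter, 7 in a separate fit and, by limma with values of exactly 0 as no value, 0 (385 unadjusted). Day 5 gave 24 with no low filter and, by limma with values of exactly 0 as no value, 0 (466 unadjusted). Day 10 gave 405 in a separate fit. The averaged effect gave 2 with the day 3 pair and 22 without day 10, 8 of these shared with the 585.

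A replicate block within day, which assumes that replicate numbers pair libraries, gave 51 genes for the Cdk9-DN effect averaged over days (46 shared), 3 for the Cdk9-DN effect at day 5, 765 for the Cdk9-DN effect at day 10, 199 for the difference of the Cdk9-DN effect between day 10 and day 4, and 3 lists. Its genes fitted without the block gave 1 for the Cdk9-DN effect at day 4 and 5 at day 5. A block across days gave 6 at day 5 and 155 for control vector day 5 against day 4. The pairing of deviations within days had correlations of 0.0146, 0.0552 and -0.0215 across genes at days 4, 5 and 10, so no block was used. Changes between days have no value under the within-day block.

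Lists passing numbered 3 with a filter at 5 FPKM and 3 with an estimated correlation. The change from day 4 to day 10 with Cdk9-DN relative to control, a ratio of 0.574, became 0.587 and 0.564 with pseudocounts of 0.1 and 5, 0.541 with no low filter, 0.564 with median-of-ratios scaling, 0.559 (0.5585) with quantile normalization, 0.622 with the minimum of 1, 0.582 (0.5815) on genes listed in all 12 libraries and 0.585 when picked in replicate 1.

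Leaving out 1 library at a time gave 326 to 511 genes for the Cdk9-DN effect averaged over days, 1 to 10 for the Cdk9-DN effect at day 4, 9 to 19 for the Cdk9-DN effect at day 5, 976 to 1535 for the Cdk9-DN effect at day 10 and 547 to 764 for the difference of the Cdk9-DN effect between day 10 and day 4. It gave 2267 to 2827 for control vector day 10 against day 4, 43 to 263 for control vector day 5 against day 4, 1545 to 2170 for Cdk9-DN day 10 against day 4 and 4 to 5 lists. The change from day 4 to day 10 with Cdk9-DN relative to control was 0.5525 to 0.5799.

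Without day 10 the averaged log2 difference turned to 0.17 for Bhlhe40, 0.20 for Ctgf, 0.0389 for Dusp5, 0.10 for Gadd45b, 0.27 for Cyr61, 0.17 for Ier3, 0.15 for Gdf15, 0.11 for Plaur and 0.0574 for Sfn. It turned to -0.0506 for Mcm2, -0.0713 for Mcm3, -0.12 for Rrs1 and -0.0579 for Ddx21, to -0.0710 for Mcm4, Cdk9-DN effect averaged over days, and to -0.0160 for Nip7, Cdk9-DN effect averaged over days, since these differences stand at day 10. The medians turned to 0.21 for the list TGF-beta response genes, averaged effect (adjusted p = 4.18e-05), and to 0.10 for the list immediate early genes, averaged effect (adjusted p = 6.06e-04). At 8.79 to 13.0 M fragments, genes under 1 FPKM in nearly all libraries were not tested, and small RNA genes, each with few fragments, moved between 0 and high values within groups.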

Other observations

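The genes in the first paragraphs were chosen after their values were seen, and the test of gene length was planned. A group of 66 genes, processed pseudogenes among them, changed in opposite directions between day 4 and day 10, with both changes called. Of these, 27 rose in control cells and fell with Cdk9-DN, and 39 fell in control cells and rose with Cdk9-DN. Day 5 did not enter this choice, and some of these genes had moved the same way with both vectors by then. Where 1 library of a group lists a gene, its call assumes that the group varies like the others. Dusp9, a phosphatase of MAP kinases, went from 2.52 ± 0.0856 to 7.24 ± 0.076 FPKM (SD, n = 2) in control cells and from 2.51 ± 0.0507 to 1.28 ± 0.212 FPKM with Cdk9-DN. Mfge8 stood at 77.9 ± 3.87 FPKM in control cells at day 10 and at 36.3 ± 1.3 FPKM with Cdk9-DN.

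Genes that rose with Cdk9-DN and fell in control cells between days 4 and 10 included Nefl, a neurofilament gene, and Insm1, a transcription factor of neuroendocrine cells. Mt1, a metallothionein that binds metals, stood at 225 ± 2.52 FPKM at day 4 and 141 ± 12 FPKM at day 10 in control cells. With Cdk9-DN it stood at 215 ± 24.7 and 279 ± 3.5 FPKM. At day 5 Mt1 lay above day 4 with both vectors, at 290 ± 22.65 FPKM in control cells and 294 ± 32.8 FPKM with Cdk9-DN. Skp2, part of a ubiquitin ligase of the cell cycle, stood at 9.47 FPKM (1 library) in control cells at day 10 and at 17.6 ± 0.667 FPKM with Cdk9-DN (difference 0.83, adjusted p = 9.14e-04). Acaa2, an enzyme of fatty acid oxidation, stood at 34.7 ± 2.06 and 53.6 ± 0.913 FPKM.

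A hypothesis was that transcripts of long genes are lower with Cdk9-DN, since P-TEFb acts on elongation. Across protein-coding genes, which are not independent replicates, Spearman's rho between locus length and the day 10 effect was 0.0112 over 2605 genes, above the negative bound set in advance. At days 4 and 5 the values were 0.055 and 8.98e-04. The hypothesis was not borne out among the genes listed, of which those with many exons were listed in fewer libraries.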
